A study of Mus musculus with 36 samples.

How the data were processed

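Poly(A) RNA-seq was deposited for 36 mouse libraries, 30 from cortex, corpus callosum and striatum and 6 from microglia sorted from forebrain. Per the submitters' processing notes, STAR, HOMER and DESeq2 were used with the genome build mm10; their versions and the counting settings are not given in the sources used here. The authors deposited whole-number read counts per gene, not normalised, for 24940 genes, each with 1 RefSeq transcript and its coordinates, and per the file headers each library with its total. A table of the same genes and libraries in TPM was not used here, because counts carry the depth that the tests need. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart here.

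Libraries were grouped by genotype, diet and region from their titles. The counts assigned to genes made up 60.1 to 84.5% of the header total in cortex, 59.5 to 77.2% in corpus callosum, 65.5 to 76.9% in striatum and 72.3 to 74.7% in microglia. Under 70% were assigned in 6 libraries: control cortex placebo 3 and PLX5622 1, control corpus callosum placebo 3 and PLX5622 2, MSA corpus callosum PLX5622 1 and MSA striatum PLX5622 2. Each region was fitted with its 4 groups together, microglia alone, and the comparison between regions on all 30 bulk libraries. Genes were kept with filterByExpr (minimum count 10), scaled with TMM, and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The tests are 2-sided. Log2 changes carry the standard error of the fit, and levels are counts scaled to 1e6 per library (CPM) with SD.

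The lists of cell type markers and pathways (32 lists, 630 genes, 2 absent from the table) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Of all list tests 220 passed with the preset correlation and 36 with an estimated correlation. Genes named in the text follow a rule. Csf1r and Mbp are always named, with Aif1, Tmem119 and P2ry12 for the diet. To these come the 6 higher and 6 lower genes of largest fold past the threshold, with mean log2 CPM of at least 2 and no overlap between groups (3 each way without the overlap condition for interactions), and up to 4 members of smallest p per list that passed. Genes without a standard symbol were counted and not named, and some results are not reported here. The comparisons, lists and naming rule, and the alternatives not marked below as chosen later, were set before the data were examined.

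A fold against a group with no counts is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval. Intervals and floors cover counting error only. The tests were run on simulated counts with the real means, spread and library sizes. At a log2 change of 1 they recovered 8% of changed genes in cortex (14393 genes), 19% in corpus callosum (15583), 24% in striatum (14610) and 81.8% in microglia (11663), and at a change of 2 they recovered 61, 82, 81 and 97%. The false share of calls was 2.67, 3.60, 5.69 and 10.1%, above the 5% aimed for in striatum and microglia. For corpus callosum against cortex (15712 genes) 24 and 80% were recovered, with 4.27% false. A shifted list was called in each simulation. Genes were drawn independently there, so the simulations cannot test the list calls under correlation between genes.

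The alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, the replicate number as a block, each library left out in turn, fits on 2 groups alone, and leaving out the control striatum PLX5622 libraries. Leaving out the libraries of low assignment, the assigned share as a covariate and a choroid plexus score as a covariate were chosen after seeing the data. That score is the mean log2 CPM of the choroid plexus list itself. A smaller change of that list's own genes with the score is therefore built in and is no test of them.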

Results

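Poly(A) RNA was sequenced from cortex, corpus callosum and striatum of male control mice and of male mice of the MBP29-hα-syn line. That line carries a transgene under a myelin basic protein promoter, which is active in oligodendrocytes, and serves as a model of multiple system atrophy (MSA). Its animals are called MSA mice here. Mice of both genotypes ate placebo chow or chow with PLX5622 (1200 mg/kg), an inhibitor of CSF1R, the receptor on which microglia depend for survival. The diet began at 4 weeks of age and, for the bulk tissue, lasted 12 weeks. Microglia of 16-week-old mice of both genotypes were also sorted from forebrain as CD11b-positive, CD45-low cells, without a diet arm. The series therefore asked what the transgene changed, what the inhibitor removed, and whether the inhibitor acted alike in both genotypes.

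Cortex had 3 libraries in each of its 4 groups. Corpus callosum had 3 libraries from placebo control mice and 2 in each other group. Striatum had 3 libraries from placebo MSA mice and 2 in each other group. Sorted microglia had 3 libraries per genotype, which makes 36 libraries, 30 of them from bulk tissue. Counts assigned to genes ranged from 4.36 to 9.79 M per library in cortex, 4.59 to 28.6 M in corpus callosum, 5.18 to 11.3 M in striatum and 5.95 to 12.1 M in microglia. Within groups, pairs of libraries differed by far more than counting noise (chi-square per degree of freedom of 4.98 to 142 over 30 pairs), so none of these pairs was a copy. The labels do not say which libraries share an animal, so p-values measure the spread between these samples. The 2 control striatum libraries of the PLX5622 group carry PLX in their title and group but a no-treatment tag. They were grouped by title. Homeostatic microglia genes summed to 75.5 and 55.5 CPM in them, against 801 and 810 CPM in the placebo control striatum libraries. These values argue against the no-treatment tag. The labels tag the microglia controls as MBP29 heterozygous and the MSA microglia as homozygous, while the protocol speaks of wild-type controls. Coordinates are those of the deposited table, which is on mm10.

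The first diet comparison asked how far PLX5622 removed microglial transcripts from the brain of control mice. In cortex it did so nearly completely. Csf1r itself (chromosome 18, 61105572 to 61131139, NM_001037859), the receptor the drug blocks, stood at 89.3 ± 34.0 CPM (SD, n = 3) on placebo and had no counts in any of the 3 treated libraries, at least 535-fold lower. The complement genes C1qb and C1qc also had no counts in treated cortex and were at least 355-fold and 242-fold lower. The fractalkine receptor Cx3cr1 (chromosome 9, 120048683 to 120068296) went from 69.2 ± 9.11 to 0.147 ± 0.255 CPM. The purinergic receptor P2ry12 fell by 7.09 ± 0.44 on the log2 scale and the microglial membrane protein Tmem119 by 5.80 ± 0.39. Of the 26 measured members of the homeostatic microglia list, 22 were lower over all genes tested and 25 adjusted over the list alone. The list's median log2 change was -6.29, or -5.96 with the 6 genes that had an all-0 group at their bound (camera, adjusted p = 3.07e-06 with an estimated correlation).

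Other myeloid genes moved in cortex too. In the complement list 4 of 15 members were lower, among them C1qa (365 times lower, 95% counting interval 125 to 1772), and the list as a whole was lower (adjusted p = 0.000701 with an estimated correlation). Border-associated macrophage genes were lower in 2 of 4 members: F13a1, a coagulation factor of macrophages, at least 9.68-fold, and the scavenger receptor Stab1 by 3.06 ± 0.59 on the log2 scale. The list held its call (adjusted p = 0.0062 with an estimated correlation). In the disease-associated microglia list 2 of 21 members were lower, the chemokine gene Ccl6 (44.3 times, counting interval 14.9 to 217) and the signalling adaptor Tyrobp (435 times, 77.7 to 17219), with a median of -0.24 over the list (adjusted p = 0.00667 with an estimated correlation). Aif1, another microglial marker, was at 4.85 ± 3.90 and 2.41 ± 2.53 CPM in placebo and treated cortex and was not called (adjusted p = 1). Mbp, which encodes myelin basic protein, was at 1684 ± 355 and 1483 ± 669 CPM and was not called either (adjusted p = 1). In all, 71 of 14600 genes passed an adjusted p of 0.05 and all 71 were lower. The count was 38 without control PLX5622 library 2 and 43 without library 3. It was 22 in a fit on these 2 groups alone, and another split of the same 6 libraries gave 738. Of 17 named genes, 13 stayed past the threshold without each library in turn.

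In control corpus callosum, the white matter tract, 60 genes were lower and 13 higher with PLX5622 out of 15881. DESeq2 called 134 lower and 30 higher, and a fit on these 2 groups alone 24 lower and 3 higher. With the replicate number as a block 16 were lower and 0 higher. Cx3cr1 went from 64.8 ± 11.6 (SD, n = 3) to 0.802 ± 0.338 CPM (n = 2), a log2 fall by 6.27 ± 0.35 (adjusted p = 5.53e-05). Csf1r fell by 6.16 ± 0.54, P2ry12 by 6.15 ± 0.45, Tmem119 fell by 6.31 ± 0.61 and the integrin gene Itgam by 6.39 ± 0.48. Tlr7, a sensor of single-stranded RNA, was at least 43.6-fold lower and Dock2, a regulator of leukocyte migration, at least 28.7-fold lower. Of the 26 homeostatic microglia genes 20 were lower, 24 adjusted over the list alone, with a median of -5.19 (adjusted p = 0.000192 with an estimated correlation). Complement genes were lower in 5 of 16 members (adjusted p = 0.0115 with an estimated correlation). Aif1 was at 6.17 ± 2.33 and 1.99 ± 2.13 CPM and was not called. The border-associated macrophage list was lower in 1 of 7 members, Stab1 (fell by 2.70 ± 0.43), and the monocyte and neutrophil list in 1 of 4, the cytokine receptor Csf3r (129 times, counting interval 35.5 to 1069), each with adjusted p = 0.0178 with an estimated correlation. The latter list summed to 16.7 ± 1.36 CPM in placebo control corpus callosum and 1174 ± 66.6 CPM in sorted control microglia. In bulk tissue it can therefore follow microglia.

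The genes that rose in control corpus callosum included 7 members of the list for the choroid plexus, the epithelium that makes cerebrospinal fluid. Ttr, its main secreted protein, rose from 257 ± 42.9 to 1307 ± 173 CPM (log2 2.35 ± 0.38, adjusted p = 0.0267). The anti-ageing gene Kl rose by 1.76 ± 0.30, the potassium channel genes Kcnj13 and Kcne2 by 2.86 ± 0.44 and 2.44 ± 0.44, and the tight junction gene Cldn2 by 3.11 ± 0.51. Of the 12 list members 12 rose adjusted over the list alone, with a median of 2.33 (adjusted p = 0.0178 with an estimated correlation). Both treated libraries had more of these transcripts than any placebo control library, with Ttr at 1429 and 1184 CPM. Striatal projection neuron genes, a check of the dissection, summed to 5798 and 1126 CPM in the same libraries. Mbp (adjusted p = 1) was at 10815 ± 2009 CPM with the diet and 14097 ± 4269 CPM without. The count of 73 was 32, 31 and 36 without control placebo library 1, 2 or 3. It was 0 with a choroid plexus score as a covariate, added after seeing the data, with Cx3cr1 then at -6.34 ± 0.72 (adjusted p = 0.118) and Ttr at 0.42 ± 0.73 (adjusted p = 1). Ttr is part of that score, so its smaller value is built in. Without each library in turn 14 of 25 named genes stayed past the threshold.

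In control striatum, 49 genes were lower and 1 higher with PLX5622 out of 14872. Csf1r went from 99.8 ± 10.5 to 0.364 ± 0.515 CPM (SD, n = 2 each), a log2 fall by 8.01 ± 0.72 (adjusted p = 0.000429). Tmem119 fell by 6.74 ± 0.36, the lysosomal membrane protein gene Laptm5 fell by 6.31 ± 0.34, Cx3cr1 fell by 7.65 ± 0.50 and C1qb 302 times (counting interval 103 to 1466). P2ry12 was 224 times lower (76.3 to 1088). Bin2, P2ry13, Fcer1g and the myeloid transcription factor gene Spi1 had no counts in either treated library and were at least 37.6-fold, 53.7-fold, 34.4-fold and 33.2-fold lower. The homeostatic list was lower in 19 of 26 members, 24 adjusted over the list alone, with a median of -6.78 (-6.18 with 4 genes at their bound; adjusted p = 0.000278 with an estimated correlation). Complement genes were lower in 5 of 14 members (adjusted p = 0.000316 with an estimated correlation). C4b (chromosome 17, 34728381 to 34743897), a complement component that reactive astrocytes also make, went the other way and rose from 49.0 ± 5.54 to 124 ± 0.425 CPM (log2 1.35 ± 0.23, adjusted p = 0.0256). Aif1 and Mbp were not called (adjusted p = 1 each), with Mbp at 6819 ± 794 and 6501 ± 1473 CPM. The count of 50 was 33 and 29 without control PLX5622 library 1 or 2. The call of C4b was lost without either placebo library (adjusted p = 0.175 and 0.375) or either PLX5622 library (0.149 and 0.178).

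Across regions, 34 genes were lower in control mice on PLX5622 in all 3 regions. Among them were Csf1r, Cx3cr1, P2ry12, Tmem119, C1qa, C1qb, C1qc, Itgam, Trem2 and Tyrobp. The regions may share animals, so this agreement need not be independent. A direct test of whether the diet effect, averaged over both genotypes, differed between regions called 0 of 16080 genes for corpus callosum against cortex and 0 for striatum against cortex in edgeR. At an unadjusted p under 0.05 the test had 355 and 420 genes, each fewer than the share of 0.05 that no effect would give. Such low counts go with a wide spread between libraries and do not show that the regions responded alike. DESeq2 called 0 and 2. The homeostatic list was shifted up in corpus callosum against cortex (median 0.66), a call lost with an estimated correlation (adjusted p = 0.689).

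The same diet was then compared in MSA mice, where it left more microglial transcript behind. In cortex Csf1r went from 125 ± 34.5 to 22.9 ± 4.29 CPM (SD, n = 3 each), a log2 fall by 2.50 ± 0.33 (adjusted p = 0.019). Cx3cr1 fell by 2.67 ± 0.35, P2ry12 by 2.80 ± 0.32, Tmem119 by 2.06 ± 0.29, Itgam by 2.54 ± 0.35, the adhesion ligand gene Selplg by 2.76 ± 0.36 and the lipid enzyme gene Lpcat2 by 2.52 ± 0.35. The homeostatic list was lower in 7 of 26 members and 20 adjusted over the list alone, with a median of -1.58 (adjusted p = 0.00204 with an estimated correlation). Genes of border-associated macrophages (median -4.27, adjusted p = 0.00506) and of MHC class II presentation (median -1.72, adjusted p = 0.0265) were lower as lists, also with an estimated correlation, though 0 of 4 and 0 of 7 members passed alone over all genes (3 and 2 adjusted over the list alone). Aif1 (4.45 ± 0.975 and 3.56 ± 0.596 CPM, adjusted p = 0.932) and Mbp (adjusted p = 0.946) were not called. In all 8 of 14600 genes passed and all 8 were lower. The count was 0 without MSA placebo library 2 or 3 or MSA PLX5622 library 1, 2 or 3, and 6 without placebo library 1. DESeq2 called 40, of which 4 were higher.

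In MSA corpus callosum, Cx3cr1 fell by 2.57 ± 0.28 (104 ± 14.0 to 17.9 ± 2.34 CPM, n = 2 each, adjusted p = 0.0174) and Itgam by 2.62 ± 0.34 (adjusted p = 0.0352). Csf1r (-2.76 ± 0.44, adjusted p = 0.0626), P2ry12 (-2.39 ± 0.36, 0.0562) and Tmem119 (-2.70 ± 0.48, 0.0887) were just above the threshold. The homeostatic list was lower with the preset correlation, at 2 of 26 members and 20 adjusted over the list alone, with a median of -2.18, and lost its call with an estimated correlation (adjusted p = 0.0533). Choroid plexus genes fell in 5 of 12 members, and in 12 adjusted over the list alone, with a median of -3.18 (adjusted p = 0.0533 with an estimated correlation). Ttr fell by 3.93 ± 0.47, Kl by 3.34 ± 0.36, the BMP antagonist gene Sostdc1 by 3.98 ± 0.49 and the folate receptor gene Folr1 by 3.55 ± 0.48. Fam83d, a mitotic spindle gene, rose by 2.15 ± 0.29 (adjusted p = 0.0352) and Col8a1, a collagen, fell by 3.36 ± 0.44. Aif1 (adjusted p = 0.847) and Mbp (0.776) were not called. The total was 11 of 15881 genes, 10 lower and 1 higher. The count was 0 without MSA placebo library 1, MSA PLX5622 library 1 or MSA PLX5622 library 3. It was also 0 with the choroid plexus score as a covariate, where errors widened because the score ran with the groups. Cx3cr1 was then at -2.47 ± 0.86 and Itgam at -2.37 ± 1.08, and Ttr at -1.03 ± 1.00 (adjusted p = 0.996 each). The score holds Ttr itself, so the smaller value of Ttr is built in.

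In MSA striatum, all 11 called genes of 14872 were lower with PLX5622. Laptm5 fell by 2.37 ± 0.24 (adjusted p = 0.00355) and Tmem119 by 2.41 ± 0.25 (34.6 ± 2.68, n = 3, to 6.48 ± 0.174 CPM, n = 2). Cx3cr1 fell by 2.28 ± 0.31, P2ry12 by 2.67 ± 0.38, C1qb by 1.97 ± 0.31, Itgam by 3.81 ± 0.53 and Lpcat2 fell by 4.01 ± 0.52. Csf1r was -2.31 ± 0.46 and was not called (adjusted p = 0.111). Homeostatic genes were lower in 7 of 26 members and 22 adjusted over the list alone (median -2.03, adjusted p = 0.0393 with an estimated correlation). Other lists were lower with the preset correlation only: choroid plexus (median -2.37), endothelial cells (-1.13), MHC class II (-0.99), complement (-0.77), pericytes and smooth muscle (-0.72), MHC class I (-0.61), pan-neuronal (-0.50) and lysosome (-0.43). With an estimated correlation their adjusted p was 0.643, 0.588, 0.189, 0.0551, 0.588, 0.304, 0.304 and 0.268. Ependymal, cell cycle and astrocyte lists were higher with the preset correlation (medians 0.91, 0.56 and 0.15) and not with an estimated one (adjusted p = 0.588, 0.304 and 0.588). Aif1 (adjusted p = 0.561) and Mbp (0.419) were not called. The count of 11 was 824 without MSA placebo library 1, 4 without placebo library 2, and 0 without MSA PLX5622 library 2 or 3. It was 0 with the share of assigned reads as a covariate. In MSA placebo library 1 striatal projection neuron genes summed to 13939 CPM, against 19996 and 20747 CPM in placebo libraries 2 and 3. Its cortical glutamatergic neuron genes summed to 6660 CPM, against 4259 and 3839 CPM. Whether this difference in tissue set the count without that library was not tested. DESeq2 called 268, 60 higher and 208 lower.

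Of the genes lower in MSA mice, 8 of 8 in cortex, 2 of 10 in corpus callosum and 9 of 11 in striatum were also lower in controls, where independent lists would share 0.0389, 0.0378 and 0.0362. Of the control mouse calls, 71 of 71, 59 of 60 and 49 of 49 had the same sign in MSA mice, with a median log2 change in cortex of -5.74 in controls and -1.60 in MSA mice. In corpus callosum these medians were -5.30 and -1.59, and in striatum -6.31 and -1.96. The genes were picked by their calls in controls, so a part of the smaller change in MSA mice is built in. Some control values rest on groups without counts, so their size depends on the fit's prior count. Of the 13 genes higher in control corpus callosum 5 were called lower in MSA corpus callosum, among them the choroid plexus genes Ttr, Kl and Kcnj13. Ttr was high in the control PLX5622 libraries (1429 and 1184 CPM) and the MSA placebo libraries (7770 and 2925 CPM). The opposite signs thus ran with the choroid plexus transcript of these libraries and need not be opposite responses to the diet.

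Whether the 2 genotypes responded differently was tested with the interaction of genotype and diet. It called microglial genes in each region. In cortex all 14 called genes were higher, that is, less reduced in MSA mice, and 12 of them were members of the homeostatic list. They included C1qc (log2 9.67 ± 0.78, adjusted p = 0.000411), Ctss (7.07 ± 0.60), Csf1r (9.71 ± 0.89), Cx3cr1 (6.33 ± 0.73), P2ry12 (4.29 ± 0.54) and Tmem119 (3.74 ± 0.49). The values of C1qb, C1qc and Csf1r rest on a group without counts, so their size depends on the fit's prior count. In striatum all 13 called genes were higher, with Laptm5 at 3.94 ± 0.41, Tmem119 at 4.33 ± 0.45, Cx3cr1 at 5.37 ± 0.60, Csf1r at 5.70 ± 0.85 (adjusted p = 0.0489) and C1qc at 4.92 ± 0.65. In corpus callosum 15 genes were higher, such as Cx3cr1 (3.71 ± 0.43, adjusted p = 0.00513), P2ry12 (3.76 ± 0.55), Gpr34 (6.96 ± 0.89) and Tyrobp (5.80 ± 0.85), while Csf1r (3.39 ± 0.65, adjusted p = 0.0946) and Tmem119 (3.61 ± 0.75, 0.155) were not called. The 27 genes lower there included the choroid plexus genes Ttr (-6.28 ± 0.60), Kl (-5.10 ± 0.47), Kcnj13 (-6.43 ± 0.67) and Folr1 (-5.86 ± 0.63). For corpus callosum DESeq2 called 37 genes higher and 83 lower, and a fit with the replicate number as a block called 0.

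C1qb, Cx3cr1 and P2ry12 had a positive interaction in all 3 regions. The regions may come from the same animals, as a check below points to, so they need not be independent repeats. With each library left out in turn, all 8 named calls stayed past the threshold in cortex, 9 of 17 in corpus callosum and 2 of 9 in striatum, Laptm5 and Tmem119. In corpus callosum Cx3cr1 stayed, while C1qb and P2ry12 were lost (adjusted p up to 0.111 and 0.154). In striatum C1qb, Cx3cr1 and P2ry12 were lost without MSA PLX5622 library 3 (adjusted p = 0.055, 0.055 and 0.285). The homeostatic list was higher in each: 12 of 26 members and a median of 4.05 in cortex (adjusted p = 0.000288 with an estimated correlation), 5 of 26 and 3.11 in corpus callosum (0.0104), 11 of 26 and 4.90 in striatum (0.0144). Adjusted over the list alone, 22, 19 and 18 members were higher, and 1 was lower in corpus callosum. The complement list was higher in cortex (3 of 15 members, adjusted p = 0.0119 with an estimated correlation) and striatum (3 of 14, 0.0144) and lost its call in corpus callosum (0.233). The choroid plexus list was lower in corpus callosum in 9 of 12 members, with a median of -5.39 (adjusted p = 0.0104 with an estimated correlation). Aif1 (adjusted p = 0.94, 0.959 and 0.922) and Mbp (0.941, 0.959 and 0.802) were not called. The cortex count ranged from 10 to 15 with a library left out. The count of 42 in corpus callosum was 27 without control placebo library 2, 64 and 384 without control PLX5622 library 1 or 2, 20 without MSA placebo library 1 and 24 without MSA PLX5622 library 1. With a choroid plexus score as a covariate, added after seeing the data, it was 0, with Cx3cr1 at 3.88 ± 1.52 (adjusted p = 1) and Ttr at -1.45 ± 1.67 (adjusted p = 1), and errors widened because the score ran with the groups. For Ttr, which is in the score, the smaller value is built in. Homeostatic genes were then at a median of 3.29 (adjusted p = 1.81e-07 with the preset correlation). The count of 13 in striatum was 8 without control placebo library 1, 7 without control PLX5622 library 2, 21 and 8 without MSA placebo library 1 or 2, and 2 without MSA PLX5622 library 3.

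The sum of the 26 homeostatic genes shows the same difference on the scale of level. In cortex it went from 925 ± 92.9 to 53.8 ± 7.89 CPM (SD, n = 3 each) in controls, which left 5.81%, and from 1048 ± 276 to 318 ± 34.7 CPM (n = 3 each) in MSA mice, which left 30.4%. In corpus callosum the diet left 9.88% in controls (969 ± 62.1, n = 3, to 95.7 ± 33.5 CPM, n = 2) and 28.4% in MSA mice (1412 ± 197 to 401 ± 80.03 CPM, n = 2 each). In striatum it left 8.12% (806 ± 6.27 to 65.5 ± 14.1 CPM, n = 2 each) and 26.8% (1067 ± 167, n = 3, to 286 ± 73.8 CPM, n = 2). The lowest treated MSA library lay 4.85, 2.89 and 3.09 times above the highest treated control library in cortex, corpus callosum and striatum. A set of resident microglia markers kept a lower median share in controls, 1.61, 1.21 and 0.801% in these regions. In MSA mice the markers kept 25.6, 17.2 and 19.1%. The share left thus depends on the genes taken, and the share of the sum is not the share of microglia that survived.

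**Figure D1:**
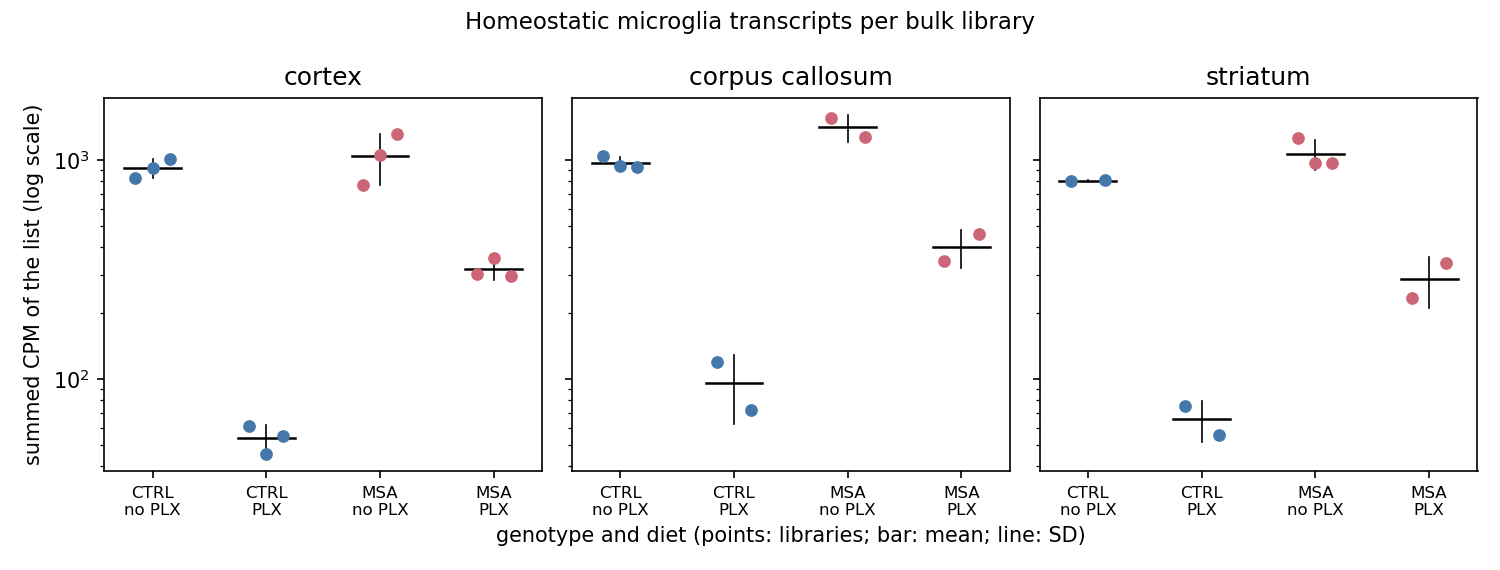
Summed CPM of the 26 homeostatic microglia genes in each bulk library (vertical axis, logarithmic), by region, genotype and diet (horizontal axis), with points for libraries and bars for the group mean ± SD. PLX5622 left 5.81%, 9.88% and 8.12% of the placebo level in control cortex, corpus callosum and striatum. In MSA mice it left 30.4%, 28.4% and 26.8%. These are shares of the summed transcript and not of the cells.

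A comparison of the genotypes under PLX5622 measured the same excess directly. In cortex all 22 called genes of 14600 were higher in MSA mice. Csf1r (22.9 ± 4.29 CPM against no counts, n = 3 each) was at least 137-fold higher, C1qb 165-fold and C1qc 130-fold at least, and the microglial genes Ly86 and Fcrls at least 32.6-fold and 32.5-fold. Cx3cr1 was 136 times higher (counting interval 37.4 to 1129), Ctss 194 times (53.3 to 1604), and Tmem119 rose by 3.99 ± 0.39 on the log2 scale. The homeostatic list was higher in 14 of 26 members, 22 adjusted over the list alone (median 3.94, adjusted p = 2.89e-05 with an estimated correlation). Complement (4 of 15 members, 0.000594), disease-associated microglia (0 of 21 members, 1 adjusted over the list alone, 0.00252) and monocyte and neutrophil genes (1 of 4, Csf3r, 0.0451) were higher as lists with an estimated correlation. Sorted control microglia also carried the monocyte and neutrophil list (1174 ± 66.6 CPM, against 14.1 ± 2.12 CPM in placebo control cortex). Its rise can therefore follow microglia. Aif1 and Mbp were not called (adjusted p = 1 each). The count lay between 17 and 26 without any single library, and was 34 without the 2 libraries of low read assignment, an alternative added after seeing the data. It was 12 in a fit on these 2 groups alone.

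In corpus callosum under PLX5622, 30 genes were higher and 1 lower in MSA mice out of 15881. Cx3cr1 was at 17.9 ± 2.34 against 0.802 ± 0.338 CPM (n = 2 each; log2 4.42 ± 0.35, adjusted p = 0.00104), C1qb at 4.42 ± 0.40 on the log2 scale, Csf1r at 4.30 ± 0.53, P2ry12 at 3.39 ± 0.44 and Tyrobp at 6.03 ± 0.71. Tmem119 was not called (3.35 ± 0.62, adjusted p = 0.0877). Homeostatic genes were higher in 12 of 26 members (adjusted p = 0.00226 with an estimated correlation), disease-associated microglia genes in 2 of 28 (10 adjusted over the list alone, 0.0155), complement genes in 4 of 16 (0.0104) and monocyte and neutrophil genes in 1 of 4 (0.0334). The list of inflammatory cytokines and signalling was higher with 0 of 17 members called alone (0.0241). The interferon response and MHC class I lists had medians of 1.19 and 1.32 and lost their calls with an estimated correlation (adjusted p = 0.055 and 0.0652), as did the choroid plexus list, which was lower (median -1.71, 0.055). The lower gene was Anln, an actin-binding protein gene (40.1 ± 6.24 against 175 ± 29.9 CPM; -2.12 ± 0.31, adjusted p = 0.0282). Aif1 and Mbp were not called (adjusted p = 1 each). The count of 31 was 72 without control PLX5622 library 2, 19 and 17 without MSA PLX5622 library 1 or 3, and 0 in a fit on these 2 groups alone. It was 1 with the choroid plexus score as a covariate, with Cx3cr1 at 4.47 ± 0.58 (adjusted p = 0.145). Left out 1 at a time, the libraries kept 8 of 15 named genes past the threshold.

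In striatum under PLX5622, 28 genes were higher and 5 lower in MSA mice out of 14872. Laptm5 was at 12.7 ± 3.25 against 0.582 ± 0.207 CPM (n = 2 each; log2 4.42 ± 0.35, adjusted p = 0.000279), Cx3cr1 at 5.92 ± 0.51 on the log2 scale, Tmem119 at 4.54 ± 0.39 and Csf1r at 6.11 ± 0.73. Fcer1g was at least 14.3-fold higher. Homeostatic genes were higher in 15 of 26 members (adjusted p = 0.0087 with an estimated correlation) and complement in 4 of 14 (0.00465). The genes lower in MSA mice were the serine protease gene Klk6 (193 times, counting interval 34.4 to 7648), Anln (-2.81 ± 0.37), the integrin gene Itgb4 (-2.32 ± 0.25), the actin-severing protein gene Gsn (-1.80 ± 0.29) and the transporter gene Abca8a (-2.90 ± 0.47). The mature oligodendrocyte and myelin list was lower with the preset correlation, in 2 of 30 members and 9 adjusted over the list alone (median -0.37), and not with an estimated one (adjusted p = 0.447). Mbp (5336 ± 975 and 6501 ± 1473 CPM, adjusted p = 0.746) and Aif1 (0.925) were not called. The count of 33 was 18 and 15 without control PLX5622 library 1 or 2, and 17 and 19 without MSA PLX5622 library 2 or 3. It was 13 with the share of assigned reads as a covariate. Of 19 named genes 9 stayed past the threshold without each library. DESeq2 called 87, 56 higher and 31 lower.

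On placebo chow, the comparison of MSA with control mice asked what the transgene alone changed. In cortex edgeR called 0 of 14600 genes, with 514 at an unadjusted p under 0.05, and DESeq2 called 3. Those 514 genes are fewer than the share of 0.05 that no effect at all would give. Such a low count goes with a wide spread between libraries and does not show that the transgene had no effect. Control placebo library 3 differed from libraries 1 and 2 with a chi-square per degree of freedom of 142 and 104, against 15.8 between libraries 1 and 2. In the simulation for cortex, 8% of genes with a log2 change of 1 were recovered. Csf1r was at 125 ± 34.5 and 89.3 ± 34.0 CPM in MSA and control cortex (adjusted p = 0.828), and Mbp at 1530 ± 640 and 1684 ± 355 CPM (n = 3 each, adjusted p = 0.949). With the preset correlation 5 lists were shifted up, the largest being striatal projection neuron genes (median 0.66), and with an estimated correlation 0 of 32 lists were (adjusted p = 0.634 for that list).

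In striatum on placebo chow, 4 genes were lower and C4b was higher in MSA mice. Klk6 (chromosome 7, 43824544 to 43832027), a protease of oligodendrocytes, fell from 16.9 ± 6.01 (SD, n = 2) to 0.267 ± 0.245 CPM (n = 3; log2 -5.97 ± 0.63, adjusted p = 0.00489). Anln fell by 3.29 ± 0.32, from 113 ± 16.2 to 11.6 ± 5.19 CPM (adjusted p = 0.00489). Hapln2, a link protein of the node of Ranvier, fell by 2.46 ± 0.32 and Carns1, carnosine synthase, by 1.53 ± 0.22. C4b rose by 1.56 ± 0.22, from 49.0 ± 5.54 to 144 ± 23.6 CPM (adjusted p = 0.0413). The mature oligodendrocyte and myelin list was lower with the preset correlation in 2 of 30 members, 7 adjusted over the list alone, with a median of -0.61 (adjusted p = 0.0903 with an estimated correlation). Mbp was at 3672 ± 1207 and 6819 ± 794 CPM and was not called (-0.89 ± 0.29, adjusted p = 0.999). The complement list was higher (median 0.73, adjusted p = 0.0375 with an estimated correlation), in 1 of 14 members. Homeostatic and disease-associated microglia genes (medians 0.42 and 0.47) lost their calls with an estimated correlation (adjusted p = 0.28 and 0.196), and Csf1r was at 132 ± 11.3 and 99.8 ± 10.5 CPM (adjusted p = 0.999). MSA placebo library 3 had Ttr at 3412 CPM, against 49.7 and 375 CPM in the other MSA placebo libraries. The choroid plexus list had a median of 3.43 (adjusted p = 0.38 with an estimated correlation). MSA placebo library 1 had cortical glutamatergic neuron genes at a sum of 6660 CPM, against 4259 and 3839 CPM in libraries 2 and 3. With the choroid plexus score as a covariate, added after seeing the data, 2 genes passed, Klk6 and Anln, while C4b was at 1.64 ± 0.22 (adjusted p = 0.0823), Hapln2 at -2.47 ± 0.36 (0.109) and Carns1 at -1.46 ± 0.24 (0.145). The total was 5 of 14872 genes. It was 2 and 3 without control library 1 or 2, and 9, 2 and 3 without MSA library 1, 2 or 3. Klk6 and Anln stayed past the threshold in each of these fits, while C4b, for instance, had adjusted p = 0.482, 0.89 and 0.179 without control library 1 or 2 or MSA library 2. A fit on these 2 groups alone called 0.

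In corpus callosum on placebo chow, 50 genes were higher and 1 lower in MSA mice out of 15881. The split depended on the fit. DESeq2 called 178 higher and 54 lower, and a fit on these 2 groups alone 203 and 70. With the assigned share as a covariate, added after seeing the data, it was 123 and 24, and with the replicate number as a block 20 and 1. The named genes included members of the choroid plexus list. Ttr (chromosome 18, 20665250 to 20674326) was at 5347 ± 3426 (SD, n = 2) against 257 ± 42.9 CPM (n = 3; log2 4.40 ± 0.41, adjusted p = 0.00256), Kl rose by 3.64 ± 0.31, the water channel gene Aqp1 by 4.63 ± 0.49, Kcnj13 by 4.31 ± 0.45 and the bicarbonate transporter gene Slc4a5 by 4.67 ± 0.64. In the choroid plexus list 10 of 12 members rose, 12 adjusted over the list alone, with a median of 3.71 (adjusted p = 0.0406 with an estimated correlation). Immune genes past the threshold were Fgl2, a fibrinogen-like protein of leukocytes (54.8 ± 22.5 against 2.40 ± 0.508 CPM; 4.50 ± 0.31, adjusted p = 0.000448), and Cd74, the MHC class II invariant chain (34.5 ± 16.4 against 2.78 ± 1.21 CPM; 3.68 ± 0.59, adjusted p = 0.0295). The growth factor gene Igf2 rose by 2.68 ± 0.35 and Cd109, a surface protein gene, by 3.16 ± 0.49. Anln fell by 2.64 ± 0.31, from 187 ± 51.0 to 29.4 ± 5.10 CPM (adjusted p = 0.00571). Csf1r (151 ± 39.0 against 82.1 ± 23.9 CPM, adjusted p = 0.537) and Mbp (8359 ± 2065 against 14097 ± 4269 CPM, 0.639) were not called.

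Several immune and glial lists were shifted in the same comparison with the preset correlation and missed the threshold with an estimated one. Among these were reactive astrocytes (median 1.35, 1 of 29 members, 14 adjusted over the list alone; adjusted p = 0.0541), disease-associated microglia (0.93, 0 of 28, 16 alone and 1 alone lower; 0.053), inflammatory cytokines and signalling (1.35, 0 of 17, 3 alone; 0.053), MHC class I (1.09, 0 of 15, 7 alone; 0.101), MHC class II (1.12, 1 of 9, 3 alone; 0.053), complement (1.04, 0 of 16, 5 alone; 0.053) and homeostatic microglia (0.54, 0 of 26; 0.39). The mature oligodendrocyte and myelin list was lower (median -0.33, 1 of 30 members; adjusted p = 0.607 with an estimated correlation). Some lists that check the dissection were higher with the preset correlation and not with an estimated one. These were meningeal fibroblasts (median 0.67, camera adjusted p = 3.75e-09) and ependymal cells (0.89, 0.00114). Striatal projection neuron genes, which also check the dissection, were lower with the preset correlation only (median -0.62, camera adjusted p = 0.00482). Pan-neuronal genes summed to 12751 ± 1959 CPM in placebo control corpus callosum and 15558 ± 2252 CPM in placebo control cortex. The corpus callosum libraries thus held neuronal transcript, and differences between them can follow the dissection. Both MSA libraries had high choroid plexus transcripts, with Ttr at 7770 and 2925 CPM. Meningeal fibroblast genes summed to 493 ± 193 CPM (SD, n = 2) in MSA and 123 ± 2.20 CPM (n = 3) in controls. The immune and glial shifts thus ran together with the markers of choroid plexus and meninges. With a choroid plexus score as a covariate, added after seeing the data, the count of 51 was 0, which for the choroid plexus genes in the score is built in. The value of Fgl2 was then 2.39 ± 0.94 and that of Anln -3.19 ± 1.19, with a wider error because the score ran with the groups. The list medians were then 0.19 for reactive astrocytes (adjusted p = 0.892 with the preset correlation), 0.26 for disease-associated microglia (0.431), 0.32 for inflammatory cytokines and signalling (0.694), -0.54 for MHC class I (0.918), 0.94 for MHC class II (0.354), -0.19 for complement (0.727) and 0.11 for homeostatic microglia (0.431), while the mature oligodendrocyte and myelin list was at -0.90 (0.0465). Meningeal fibroblasts (1.74, 0.00214) and immediate early genes (0.96, 0.0465) also passed with the score, and ependymal cells (0.41, 0.431) did not. The count was 29, 10 and 14 without control library 1, 2 or 3 and 7 without MSA library 1. Anln was lost without MSA library 1 or 2 (adjusted p = 0.0976 and 0.068), and Cd74 without any 1 of the 5 libraries (adjusted p up to 0.226), while Fgl2, Kcnj13, Kl and Ttr stayed past the threshold.

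Sorted microglia were compared between genotypes to see the response of the cells themselves. Genes of the disease-associated state rose. Axl, a receptor for apoptotic cells, rose from 21.6 ± 1.41 to 131 ± 27.1 CPM (SD, n = 3 each; log2 2.61 ± 0.16, adjusted p = 0.000472). The β-glucan receptor gene Clec7a rose by 1.41 ± 0.15, the oxidase subunit gene Cybb by 1.34 ± 0.16 and the lysozyme gene Lyz2 by 0.96 ± 0.10. In the disease-associated microglia list 6 of 26 members were higher, 16 adjusted over the list alone, with a median of 0.68 (adjusted p = 0.00229 with an estimated correlation). The homeostatic list had a median of -0.09 with 0 of 26 members called, lower with the preset correlation (adjusted p = 0.0159) and not with an estimated one (0.431). The drug target Csf1r was at 12160 ± 661 and 13209 ± 374 CPM in MSA and control microglia (adjusted p = 0.552). Mbp was at 8.89 ± 2.29 and 28.1 ± 18.1 CPM (adjusted p = 0.472).

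The largest rises were outside that list. Scoc (chromosome 8, 83434492 to 83442662), a Golgi-associated coiled-coil protein gene, went from 1.34 ± 0.525 to 70.2 ± 3.00 CPM (log2 5.69 ± 0.16, adjusted p = 5.38e-08). Its neighbour Clgn, a chaperone gene (83389842 to 83428552), was 92.1 times higher (counting interval 31.1 to 450), and Rnf150, a ubiquitin ligase gene (82863356 to 83091271), rose by 3.10 ± 0.18. The proteoglycan gene Cspg4, known from oligodendrocyte precursors and pericytes, rose by 4.64 ± 0.29, from 0.388 ± 0.130 to 10.3 ± 0.650 CPM, the endothelial receptor gene Flt1 by 3.12 ± 0.32, and the adhesion receptor gene Cd44 by 1.31 ± 0.22. Among the genes that fell were Lgi4, a secreted glial protein gene (-3.22 ± 0.15, 119 ± 3.798 to 12.5 ± 3.34 CPM), the calcium channel genes Cacna1a (-1.01 ± 0.06) and Cacng8 (-1.38 ± 0.24), the protease gene Htra3 (-0.96 ± 0.12) and the amino acid transporter gene Slc1a4 (-0.95 ± 0.16). Hspa1a, an inducible heat shock protein, fell by 2.13 ± 0.35 and the chaperone gene Hsp90aa1 by 0.84 ± 0.11. The heat shock and ER stress list was lower in 2 of 16 members, 10 adjusted over the list alone (median -0.29, adjusted p = 0.0636 with an estimated correlation). Of the lists of other cell types, mature oligodendrocytes (median -0.04), astrocytes (-0.26) and pan-neuronal genes (-0.08) were not called (adjusted p = 0.151, 0.206 and 0.464). Endothelial (median 0.08, 1 of 7 members), choroid plexus (0.55) and reactive astrocyte genes (0.36) were higher with the preset correlation and not with an estimated one (adjusted p = 0.368, 0.546 and 0.215). In all 50 genes were higher and 22 lower out of 11810. The count of 72 was 170, 46 and 31 without control library 1, 2 or 3, and 33 without MSA library 2. Of 17 named genes 12 stayed past the threshold without each library, and the count was 9 with the share of assigned reads as a covariate, added after seeing the data.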

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

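The tests of explanations given here, and the counts over other splits of the libraries, were chosen after the results were seen, while the interaction itself was planned. The test for other cells in the sort replaced an earlier form after that form's result was seen. The interaction test of genotype and diet had 14 genes past the threshold in cortex, 42 in corpus callosum and 13 in striatum, and the homeostatic microglia list had medians of 4.05, 3.11 and 4.90 on the log2 scale. Of the 42 genes 27 were lower, among them choroid plexus genes, and the count was 0 with a choroid plexus score as a covariate, added after seeing the data. The score ran with the groups, so errors widened: Cx3cr1 went from 3.71 ± 0.43 to 3.88 ± 1.52, Ttr from -6.28 ± 0.60 to -1.45 ± 1.67, and the median of the homeostatic list from 3.11 to 3.29. Ttr is part of the score, so its smaller value is built in and tests nothing.

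The first pattern is the microglial transcript left in MSA mice under PLX5622. More microglia before the diet would need a like excess on placebo chow, but the largest ratio of MSA to control there was 1.46. A single mislabelled or mixed library would leave the others in the control range, but the lowest treated MSA library was at least 2.89 times the highest treated control library in every region. Myeloid cells from blood in place of all microglia would lack resident markers, but these kept a median of 25.6, 17.2 and 19.1% of their level in MSA cortex, corpus callosum and striatum, against 1.61, 1.21 and 0.801% in controls, while general myeloid markers kept more, 35.1, 22.4 and 25.9% against 0.115, 1.60 and 0.407%, so a part from blood stays open. A lower survival effect of the drug in MSA mice may explain the excess, and so could a difference in drug exposure or food intake, neither of which was measured here.

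The second pattern is the choroid plexus transcripts in placebo MSA corpus callosum. Carried-over choroid plexus tissue would keep its genes in 1 ratio. Over the 5 bulk libraries above 1000 CPM of Ttr, which come from 3 groups, the log2 ratio of the other genes to Ttr had an SD of 0.376, while log2 Ttr had an SD of 1.08. The 83.3% of the list past the threshold is the pattern itself and cannot test whether its genes were induced without the tissue. The values are consistent with tissue carried over in dissection, and induction without the tissue and enlarged or displaced choroid plexus in MSA mice stay open.

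The third pattern is a run of called genes in MSA microglia on chromosome 8. All 5 tested genes between Rnf150 and Scoc (82863356 to 83442662) were higher, including Tbc1d9 (log2 0.41) and Elmod2 (0.66). Random sets of 72 tested genes had as many called genes within 1 Mb with a permutation p of 0.001 (10000 sets, highest 6). Neurons as the source of Scoc would need Snap25 at 5347 CPM, and 1.78 CPM was seen. Oligodendrocyte precursors as the source of Cspg4, which lies outside the run, would need Pdgfra at 24.4 CPM. Of that level 2.14% was seen (0.523 CPM). Other cell types, and sources of Rnf150 and Clgn, were not tested. Choroid plexus transcript was in the sort, with Ttr at 761, 1410 and 1026 CPM in MSA and 468, 1073 and 661 CPM in control libraries. A linked difference active in every cell type would show in bulk tissue, where the median log2 change of Rnf150, Clgn and Scoc was -0.0163. A difference near this segment that acts in microglia may explain the run, such as a strain segment or the place of the transgene. That place is not given in the sources used here. By their labels the controls are heterozygous and would carry 1 copy of the transgene. A change in proportion to copies would then be near a log2 of 1, against 5.69 for Scoc. The place of the transgene would thus need wild-type controls, as the protocol states, and the sources leave the genotype of the controls unsettled.

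Other splits of the same libraries were counted for comparisons with 3 libraries in each group. In the cortex interaction 1 of 60 splits, the real one, gave as many as 14 calls, and the highest other gave 3. These splits shuffled the libraries over all groups, which also breaks the diet effect. They cannot test the interaction alone, so chance is not excluded by them. The other designs have 10 splits, too few for a share under 0.05. Cortex on placebo chow had 0 calls and the highest other split 1, so 10 of 10 splits gave as many. For PLX5622 in control cortex 2 splits gave as many as 71, and the other gave 738; it set placebo 1 and 2 with PLX5622 3 against the rest, which held both libraries of low assignment, and points to a structure of the samples. For PLX5622 in MSA cortex 1 split gave as many as 8 and the highest other gave 0. For the genotypes under PLX5622 1 split gave as many as 22 and the highest other gave 0. In microglia 1 split gave as many as 72 and the highest other gave 6.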

How the results depend on the processing

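The alternatives with low-assignment libraries left out, the assigned share and the choroid plexus score were chosen after seeing the data; the others were planned. Where a value changed, the cause was not tested. A library left out of a group of 2 leaves 1 sample, which is assumed to vary like the others. With RLE size factors every count stayed within 1.5 times, and all 196 called named genes stayed past the threshold, as they did with DESeq2. With no filter 189 of 196 did, with each library left out 822 of 1134 tests, with the block 123 of 196, in fits on 2 groups 105 of 144, without low-assignment libraries 142 of 179, with the assigned share 163 of 196 and with the choroid plexus score 103 of 196, where 3 others changed sign. At these depths and group sizes 8 to 24% of simulated genes with a log2 change of 1 were recovered in the bulk regions.

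DESeq2 called 3, 128, 40, 51 and 31 genes in cortex (placebo genotype, PLX5622 in controls, PLX5622 in MSA, genotype under PLX5622, interaction), 232, 164, 137, 137 and 120 in corpus callosum, 31, 99, 268, 87 and 22 in striatum, 174 in microglia and 2 for striatum against cortex, with an overlap of diet calls of 123 against 19. Of these 1, 0, 4, 48 and 30 were higher in cortex, 178, 30, 20, 111 and 37 in corpus callosum, 10, 3, 60, 56 and 21 in striatum and 99 in microglia. With no low-count filter the counts were 89 (placebo genotype), 48 (PLX5622 in MSA), 59 (genotype under PLX5622) and 65 (interaction) in corpus callosum, 17, 84, 89, 51 and 24 in striatum, 254 in microglia and an overlap of 51. Fits on 2 groups alone gave 22, 19 and 12 in cortex (PLX5622 in controls, in MSA, genotype under PLX5622), 273, 27, 48 and 0 in corpus callosum (placebo genotype, both diet effects, genotype under PLX5622), 0 for striatum on placebo chow and an overlap of 30. With an estimated correlation 36 lists passed instead of 220.

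Same-numbered libraries within a region did not all deviate together (median correlation -0.06 in cortex, -0.04 in corpus callosum, 0.10 in striatum, 0.03 in microglia; 5 of 10 pairs over 0.1 in striatum), so the numbers were not taken as pairs. Across regions 12 of 25 pairs correlated over 0.1; in groups of 3, where own and other numbers can be compared, 4 of 6 correlated best with their own number. Between regions the block was genotype, diet and number, with a consensus correlation of 0.074 and 0 calls in both comparisons. With the replicate block the counts were 1 (PLX5622 in MSA) and 14 (genotype under PLX5622) in cortex, 21, 16, 0, 3 and 0 in corpus callosum, and in striatum 11 (placebo genotype), 1349 (PLX5622 in MSA, 792 higher and 557 lower), 1908 (genotype under PLX5622, 1130 higher and 778 lower) and 44 (interaction, 36 higher and 8 lower), with an overlap of 36; no other count moved by over 1.5 times. With the block Aif1 in striatum against cortex was 0.0326, Mbp was -0.0189 for PLX5622 in MSA corpus callosum and 0.16 for genotype under PLX5622 in striatum.

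With the assigned share as a covariate the counts were 18 for PLX5622 in MSA cortex, 147, 135, 42, 85 and 88 in corpus callosum, 0 and 13 in striatum (PLX5622 in MSA, genotype under PLX5622) and 9 in microglia. Mbp was then 0.0221 for genotype under PLX5622 in corpus callosum, and Aif1 -1.60 for that comparison in striatum. Without low-assignment libraries the counts were 16 and 34 in cortex (PLX5622 in MSA, genotype under PLX5622), 93, 151, 33, 74 and 160 in corpus callosum, 3, 0 and 17 in striatum (placebo genotype, PLX5622 in MSA, genotype under PLX5622), with an overlap of 33. Aif1 was then 0.21 for PLX5622 in control cortex, -0.54 for the cortex interaction and -0.98 for genotype under PLX5622 in striatum; Mbp was 0.22 for corpus callosum against cortex and 0.0892 for genotype under PLX5622 in corpus callosum. Without the control striatum PLX5622 libraries striatum had 3 (placebo genotype) and 17 (PLX5622 in MSA).

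With the choroid plexus score the counts in corpus callosum were 0, 0, 0, 1 and 0, and in striatum 2 (placebo genotype) and 8 (interaction). In placebo corpus callosum Cldn2 was then -0.00465, Slc4a5 -0.34, MHC class I -0.54, interferon response -0.64, complement -0.19, trophic factors 0.42 and striatal projection neurons 1.06. With that score Kcnj13 was 0.10 and Aif1 0.38 for PLX5622 in MSA corpus callosum, and Mbp 0.31 for genotype under PLX5622 there. Cldn2, Slc4a5 and Kcnj13 are in the scored list, so their smaller values are built in. The score ran with the groups, so errors widened: Cx3cr1 for PLX5622 in controls went from -6.27 ± 0.35 to -6.34 ± 0.72.

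With each library left out, counts ranged in cortex from 0 to 0, 38 to 64, 0 to 6, 17 to 26 and 10 to 15 in the order above, in corpus callosum from 7 to 54, 31 to 93, 0 to 12, 17 to 72 and 20 to 384, in striatum from 2 to 9, 29 to 46, 0 to 824, 15 to 19 and 2 to 21, in microglia from 31 to 170, and between regions from 0 to 0 and 0 to 1. Aif1 ranged from -1.37 to 0.29 and -0.70 to 0.59 for corpus callosum and striatum against cortex, -0.24 to 2.00 for the cortex interaction, -0.98 to 0.96 for genotype under PLX5622 in striatum and -1.77 to 0.31 for its interaction. Csf1r for striatum against cortex ranged from -0.024 to 2.91. Mbp ranged from -0.21 to 0.11 for corpus callosum against cortex, -0.31 to 0.26 for genotype under PLX5622 in corpus callosum, and in cortex -0.48 to 0.14 (PLX5622 in controls), -0.11 to 0.49 (in MSA), -0.0524 to 0.57 (genotype under PLX5622) and -0.42 to 0.17 (placebo genotype), and -0.31 to 0.14 for PLX5622 in control striatum.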

Other observations

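The tests in this part were chosen after the results were seen. In MSA microglia, Hsp90ab1 was at -0.79 on the log2 scale (edgeR, adjusted p = 0.00107), Stip1 at -0.71 (0.0175), Fkbp4 at -0.57 (0.039) and Ahsa1 at -0.51 (0.0209), while Dnajb1 (-0.15, 0.711) and Hspa8 (-0.41, 0.872) were not called. Itgax was at 1.24 (0.0123), Lgals3 at 2.065 (0.0276), Pdcd1 at 2.23 (0.000617) and Lilrb4a at 1.755 (0.0063). Apoe (1.57, 0.0593), Lpl (2.87, 0.0593), Spp1 (3.10, 0.102) and Trem2 (0.05, 0.865) did not pass. These genes were picked after their values were seen.

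Whether libraries of the same genotype, diet and number came from 1 animal was tested with genes that split the bulk libraries into high and low. Over 15 such genes, same-numbered libraries of different regions lay on the same side in 80.9% of comparisons, against a median of 53.9% and a highest of 76.6% with shuffled numbers (permutation p = 0.001, the smallest that the shuffles run here can give). An earlier form of the test with 16 genes gave 56.7% against a highest of 54.9%, and the form reported here was set after that result. The agreement came from the 6 genes picked as those on the same side in all of their comparisons, 78 in number. The other 9, several of them genes of cortical neurons, did so in 36 of 63. Hmgn2, 1 of the 6, was low in 11 and high in 19 bulk libraries. The 6 genes were picked by their agreement, so they add no support of their own. The agreement over all 15 genes is what 1 animal per number across regions would give, which the labels do not state.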
